A study of Mus musculus with 12 samples.

How the data were processed

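The series covers AGO2-bound RNA of mouse cerebella at P7 and P15, with 2 miRNA, 2 target and 2 input libraries per age. Per the labels' protocols, homozygous conditional Spy3-Ago2 mice were given an AAV with Cre under L7, AGO2 was pulled down from cerebella with HaloTag-SpyCatcher3 on HaloLink resin, gel pieces between 70 and 150 kDa were taken, adapters with random bases were ligated to both RNA ends, and libraries were sequenced in single-end runs. The input libraries, the P7 target libraries and P15 target replicate 1 were not analysed on their own here; both peak lists of the series are treated as pooled over the libraries of their age, which the labels do not state outright. The list deposited with P15 target replicate 2 has the base name of the P15 list of the series but holds 1624 peaks against 5173, and what sets them apart is not stated.

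The miRNA files hold counts per mature miRNA as deposited by the authors, without normalisation. Per the submitters' processing notes UMI-tools, cutadapt 2.10, STAR 2.5.2a, Bowtie2 2.4.2, DESeq2 1.36.0, deepTools 3.1.3 and the build mm10 were used, with no role or order given. The names of the count files carry a word read here as not collapsed by molecular identifier, so amplified copies may be counted more than once. The unmapped row of each count file was 0. The deposited peak lists give start, end and strand of each peak; the score the authors' lists carry is 0 in every entry, so peaks could not be ranked. The peak caller and its thresholds are not given in the sources used here. Peak numbers run up to 12835 and 15560 in the P7 and P15 lists of 4884 and 5173 peaks, so the lists are parts of longer numbered lists.

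Samples were grouped by the labels. CPM were computed from library totals of 13059 and 6828 (P7) and 169054 and 94132 (P15). miRNAs passing filterByExpr (159) were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM, no block, Benjamini-Hochberg, threshold 0.05); lists were tested with camera (limma 3.58.1, preset correlation) where at least 3 members were measured, 7 of 16 lists. Replicates of an age had log2 CPM correlations of 0.785 (P7) and 0.900 (P15), and differed by more than sampling noise (chi-square over degrees of freedom 3.73 and 19.3). The fit was tested on simulated counts with 40 changed miRNAs in each of 20 draws, a number set by the 159 miRNAs tested; false calls averaged 0.15 to 1.25 per draw.

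Peaks were located on the GENCODE M21 annotation of mm10 on the same strand, in the order 3' UTR, coding exon, 5' UTR, other exon, intron, outside genes. Sequence came from annotated transcripts, since no genome sequence was used here, for 73.4% of P7, 80.6% of P15 and 44.3% of replicate 2 list peaks; peaks outside exons were not searched. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 was used. Per family the larger of the 2 McNemar p-values (upstream and downstream flank) was taken, set to 1 where the peak share did not lie on the same side of both flanks; this reading of the planned comparison was chosen after the first results were seen, and neither flank alone gave a call. All 46 seeds were found in their precursor in the annotation. The seed test was tried on simulated data with sites of 3 families planted in real peak sequences, 10 draws each; no other family was called. Shares have exact binomial intervals at 95%.

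The text names miR-206-3p; the 10 most abundant miRNAs at each age; up to 10 called miRNAs per direction by size of change with a mean CPM of at least 10 and no overlap between ages; up to 4 members of each list by abundance; the 10 genes with most peaks at each age (ties by alphabet); the peaks of the 4 genes named by the study; up to 4 list members with most peaks; and the families with the smallest p. A planned choice of peaks by score was not possible. Values of only some of these are printed, the rest summarised. Alternatives covered scaling, filters, tests, each library left out, the replicate number as a block, site types, backgrounds, overlap rules and the replicate 2 list. The gene lists and miRNA lists were written before the data were examined, as were the tests, the naming rule and most alternatives.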

Results

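Small RNAs and target RNAs bound to AGO2 were collected from mouse cerebella in which Cre, driven by the Purkinje cell promoter L7, had switched on a Spy3-tagged AGO2. Purkinje cells are the output neurons of the cerebellar cortex. Cerebella were taken at P7 and P15, ages between which Purkinje cell dendrites grow and synapses form. The series holds 12 libraries in 6 groups of 2, with a miRNA, a target and an input library for each age and replicate. The 4 miRNA libraries were analysed as counts per mature miRNA, and the target libraries as 1 list of peaks for each age plus a separate list deposited with P15 target replicate 2, called the replicate 2 list here. Whether that list holds the peaks of this replicate alone or another version of the P15 list is not stated, so comparisons with it are comparisons of lists, not of replicates. Input libraries were not analysed here. The P7 miRNA libraries held 13059 and 6828 counts over 1978 listed miRNAs, and the P15 libraries held 169054 and 94132 counts. Depth therefore differed with age, and 3 counts, the limit that a count of 0 allows, corresponded to 229.7 and 439.4 CPM (counts scaled by the library total) at P7 but to 17.75 and 31.87 CPM at P15. The labels do not say which animals gave each library. The p-values of the miRNA tests and the interval of a log2 change therefore measure only the spread between these libraries. Exact intervals of shares and the floors cover counting error only.

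Which miRNAs were loaded in AGO2 was asked first. At both ages miR-124-3p, a miRNA of neurons, was the most abundant, with 34.8% ± 1.60 of counts at P7 and 33.8% ± 1.76 at P15 (SD, n = 2 libraries each). The neuronal miR-9-5p followed with 11.5% ± 1.42 at P7 and 11.4% ± 0.00331 at P15. At P7 miR-138-5p took 7.42% ± 0.814, miR-125b-5p 6.91% ± 0.480 and miR-127-3p, from the imprinted Dlk1-Dio3 locus, 4.91% ± 0.653. At P15 these 3 took 7.36% ± 0.891, 7.86% ± 1.17 and 3.83% ± 0.706. miR-6240, among the 10 most abundant at P7, had counts of 95 and 198 at P7 and of 205 and 0 at P15. miR-125a-5p took 1.93% ± 0.0768 at P7 and 1.43% ± 0.0443 at P15, and miR-1983 took 0.530% ± 0.121 and 0.857% ± 0.0441.

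The lists of miRNAs typical of other cells named here each took at most 0.280% of counts on average at either age. No list of granule cell miRNAs was included, so these shares do not measure the purity of the Purkinje cell material. The 5 members of the miR-200, miR-141 and miR-429 family, known from epithelia, had no count in any of the 4 libraries. The microglial and blood-cell list and the erythroid list had no count at P7, which at that depth allows up to 229.7 and 439.4 CPM, and at P15 they reached 0.00414% and 0.00355% of counts in replicate 1 and 0 in replicate 2. The endothelial and mural list took 0.0449% ± 0.00142 at P7 and 0.0224% ± 0.0152 at P15. The oligodendrocyte list took 0.280% ± 0.0176 and 0.277% ± 0.109, of which miR-219a-5p gave 0.269% and 0.270%. In CPM miR-219a-5p averaged 2690 at P7 and 2702 at P15, above the 1603 and 1916 of miR-206-3p, the miRNA the study followed. The ciliated-cell list took 0.0335% ± 0.0148 and 0.00792% ± 0.00219, and the miR-183 cluster 0.00766% ± 0.0108 and 0.00602% ± 0.00350. In the oligodendrocyte and endothelial lists 1 member each had enough counts to test, miR-219a-5p and miR-126a-3p, and neither passed; the other lists of this paragraph had no such member.

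The comparison of P15 with P7 asked which AGO2-bound miRNAs changed as Purkinje cells matured. The 3 members of the miR-29 family rose. miR-29b-3p was higher at P15 by 2.65 on the log2 scale (SE 0.30, adjusted p = 0.000538), miR-29c-3p by 2.27 (SE 0.28, adjusted p = 0.000705) and miR-29a-3p by 1.82 (SE 0.28, adjusted p = 0.00285). Together they took 5.72% ± 0.899 of counts at P7 and 17.4% ± 2.74 at P15 (SD, n = 2), with 15.5% and 19.3% in the P15 libraries against 5.08% and 6.36% in the P7 libraries. Precursors of the family lie in 2 clusters, with Mir29a and Mir29b-1 on chromosome 6 (31062660 to 31062747 and 31063023 to 31063093, minus strand) and Mir29b-2 and Mir29c on chromosome 1 (195037040 to 195037120 and 195037547 to 195037634, plus strand) in mm10, and miR-29b-3p reads do not tell its 2 precursors apart. miR-149-5p fell by 2.24 (SE 0.48, adjusted p = 0.0313) and miR-27a-3p fell by 2.43 (SE 0.56, adjusted p = 0.0424), on counts of 72 and 56 against 142 and 93 for miR-149-5p, and of 24 and 8 against 33 and 16 for miR-27a-3p.

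The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 159 miRNAs. It called 5 miRNAs, 3 higher and 2 lower at P15, while 36 had an unadjusted p under 0.05. DESeq2 called 13, 8 higher and 5 lower, and these included all 5. The TMM factors shifted log2 changes by 0.631 against library totals, with a median change of 0.11 in place of -0.54, so changes are relative to that scaling. With totals the 5 calls kept their direction, and 7 were called, 3 higher and 4 lower. Without a low-count filter 16 were called and with a mean CPM of at least 10 the number was 22, while it was 18 without P7 replicate 1, 18 without P7 replicate 2, 12 without P15 replicate 1 and 6 without P15 replicate 2. miR-27a-3p was not called without P7 replicate 1, without P15 replicate 1 or without P15 replicate 2, nor in the draw of median call count with the P15 libraries thinned to the P7 depth, although 2 of the 5 draws kept all 5 calls, and its adjusted p ranged from 2.38e-06 to 0.400 over the alternatives.

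miR-206-3p, the miRNA the study followed, had 17 and 13 counts at P7 and 391 and 143 at P15. Its share was 0.160% ± 0.0426 at P7 and 0.192% ± 0.0561 at P15 (SD, n = 2). The log2 change was 0.90 (SE 0.52, 95% interval -0.24 to 2.05, adjusted p = 0.366 in edgeR), and 0.28 with library totals, so a difference was not detectable with these 4 libraries. Its mature form starts with TGGAAT, the bases with which the fixed part of the 3' adapter also starts. Of the other miRNAs of its muscle-type list, miR-133b-3p took 0.985% ± 0.0470 at P7 and 0.635% ± 0.0321 at P15, miR-1a-3p 0.184% ± 0.0111 and 0.0773% ± 0.00481, and miR-133a-3p 0.183% ± 0.0525 and 0.0643% ± 0.00976. None of the 4 tested members passed, and also none did adjusted over the list alone. The precursor Mir206 lies on chromosome 1 from 20679010 to 20679082 on the plus strand. In tests on simulated counts of 159 miRNAs at these depths, the fit recovered 0.5% of 2-fold, 24.1% of 4-fold and 77.9% of 8-fold changes.

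**Figure D1:**
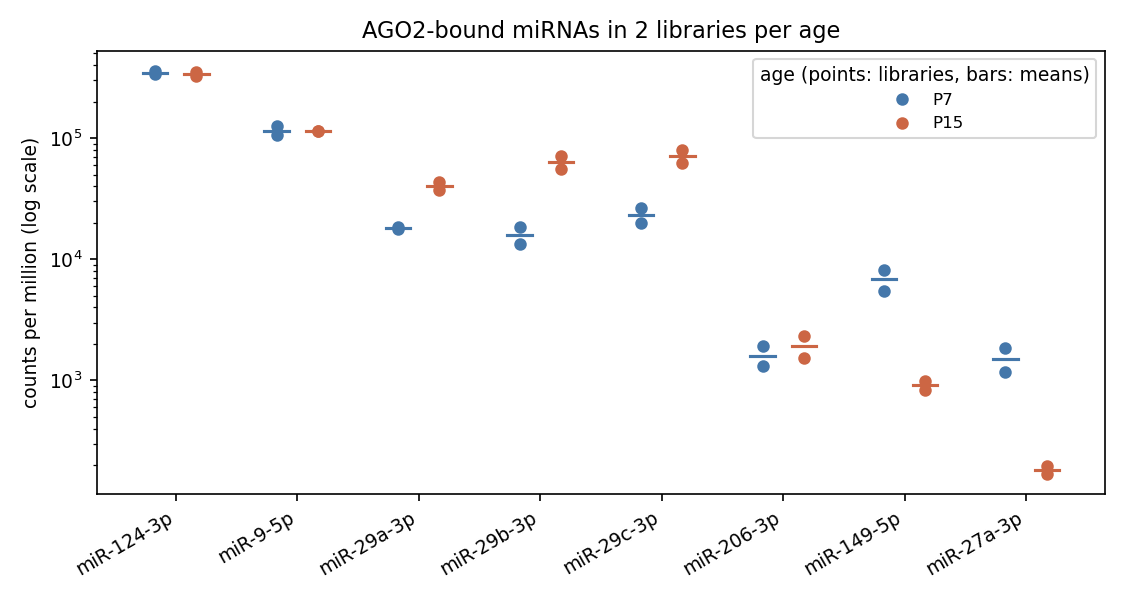
CPM (log axis) of 8 miRNAs in the 2 libraries of each age, with points for libraries and short bars for their means. miR-29a-3p, miR-29b-3p and miR-29c-3p lie higher in both P15 libraries than in both P7 libraries, miR-149-5p and miR-27a-3p lie lower, and the libraries of the ages overlap for miR-206-3p in this CPM from library totals, though not after TMM scaling (1069 and 1532 at P7, 2725 and 2079 at P15).

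Among lists fixed beforehand, only the miR-29 family passed. Its 3 members all rose, and camera gave an adjusted p of 0.00954 over 7 lists with a preset correlation, but adjusted p = 0.795 with an estimated correlation and 0.121 with fry. The call was lost without P7 replicate 1, with an adjusted p of 0.150, and over the alternatives the adjusted p ranged from 0.000905 to 0.795. In the miR-30 family none of 5 tested members passed over all miRNAs and 1 was higher adjusted over the list alone; miR-30c-5p had a log2 change of 1.56 (adjusted p = 0.0771) and miR-30d-5p of 0.30. In the pan-neuronal list none of 7 tested members passed and 3 were higher adjusted over the list alone. Its miR-124-3p, miR-9-5p and miR-138-5p had log2 changes of 0.60, 0.64 and 0.65, which were -0.04, -0.01 and -0.01 with library totals. None of 8 let-7 and miR-98 members passed, with 1.34 for let-7a-5p and 0.67 for let-7f-5p. None of 28 miRNAs of the Dlk1-Dio3 locus passed, with a median log2 change of -0.08, nor did any of the 4 tested miR-181 members, such as miR-181b-5p at -1.20; the median of this family was 0.37 while camera's direction was down. The camera adjusted p was 0.171 for the miR-30 family, 0.529 for let-7 and miR-98, 0.710 for the Dlk1-Dio3 locus, 0.797 for the muscle-type list and 0.958 for both the pan-neuronal list and the miR-181 family, and over each list alone no let-7, Dlk1-Dio3 or miR-181 member passed either. The activity-linked list had 2 tested members, miR-132-3p at -2.09 and miR-134-5p at -1.79, and neither passed. The clusters of miR-17 to miR-92 and miR-106b to miR-25, linked to dividing progenitors, took 0.108% ± 0.0125 of counts at P7 and 0.0423% ± 0.00717 at P15, with no member deep enough to test.

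Where AGO2 lay on RNA was read from the peak lists. The P7 list held 4884 peaks with a median width of 48 nt and the P15 list 5173 with a median of 51 nt. They lay in 1665 and 1810 genes, of which 935 had peaks at both ages. Of the P7 peaks 1392 (28.5%, exact 95% interval 27.2 to 29.8) overlapped a P15 peak on the same strand by at least 1 nt, and of the P15 peaks 1418 (27.4%, 26.2 to 28.6) overlapped a P7 peak. Overlap depended on location. Among P7 peaks it was 62.4% outside genes, 52.3% in introns, 46.2% in 3' UTRs and 13.3% in coding exons. Among P15 peaks it was 69.0%, 69.1%, 18.8% and 23.4% in the same order. No test compares the ages here, since each list is treated as pooled over its libraries and replicates cannot be compared. With the P15 replicate 2 list in place of the P15 list, 18.3% of P7 peaks and 54.9% of the 1624 peaks of that list overlapped. In that list the share was 68.1% outside genes, 74.1% in introns, 39.1% in 3' UTRs and 46.8% in coding exons. Between the P15 lists, 20.6% of the P15 peaks overlapped the replicate 2 list and 65.3% of the replicate 2 list overlapped the P15 list, so a peak listed at 1 age only is a peak without an overlap in the other list, not a site shown to be bound at 1 age.

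Peaks at P7 lay mostly in coding exons, and at P15 most often in 3' UTRs, the part of an mRNA where most known miRNA sites lie. At P7 2943 peaks (60.3%, exact 95% interval 58.9 to 61.6) lay in coding exons and 1005 (20.6%, 19.5 to 21.7) in 3' UTRs. At P15 1694 (32.7%) lay in coding exons and 2580 (49.9%, 48.5 to 51.2) in 3' UTRs. Peaks listed at 1 age only differed further: 55.8% of 3755 P15-only peaks and 15.5% of 3492 P7-only peaks lay in 3' UTRs, against 34.5% and 73.1% in coding exons. Both differences passed Fisher's exact test, two-sided, with adjusted p-values over 6 classes of 2.84e-291 and 2.81e-242; peaks are not replicates of an age, so the test compares the lists. Introns held 2.41% of P7-only and 1.12% of P15-only peaks (adjusted p = 5.95e-05), regions outside genes 6.59% and 4.55% (adjusted p = 0.000254), other exons 1.37% and 2.37% (adjusted p = 0.00222) and 5' UTRs 1.09% and 1.62% (adjusted p = 0.0542). With the P15 replicate 2 list the 3' UTR difference was 12.9 points in place of 40.3, with 25.2% of all peaks of that list in 3' UTRs, 12.5% in coding exons and 41.9% outside genes, and the differences of introns and of regions outside genes turned. For peaks wider than 30 nt the difference outside genes turned, while introns (adjusted p = 1.0) and other exons (adjusted p = 0.0664) no longer passed, and in genes with peaks at both ages neither introns (adjusted p = 0.0622) nor other exons (adjusted p = 0.530) passed. Bases matching the start of the 3' adapter, TGGAAT, began 0 to 5 nt after the end of 3.05% of P7, 2.78% of P15 and 14.8% of replicate 2 list peaks with enough sequence.

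**Figure D2:**
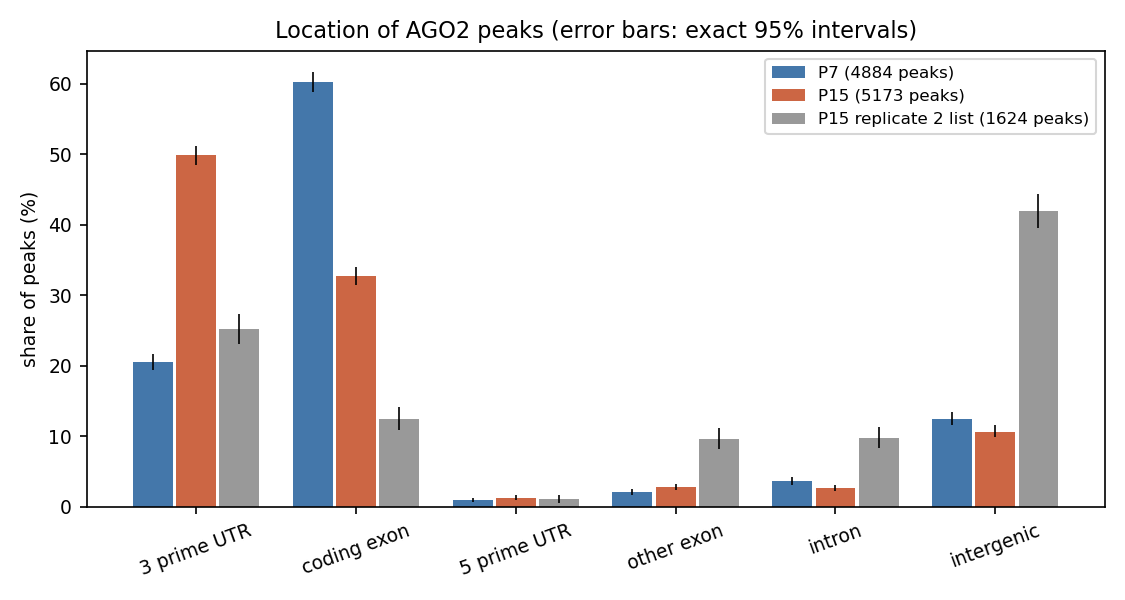
Share of peaks (percent, axis from 0) in 6 classes of location for the P7, P15 and P15 replicate 2 lists, with exact 95% binomial intervals as error bars. Coding exons hold 60.3% of P7 and 32.7% of P15 peaks, 3' UTRs hold 20.6% and 49.9%, and 41.9% of the replicate 2 list lies outside genes.

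Adcy1 had the most peaks at both ages. At P15 Adcy1, an adenylyl cyclase, had 76, followed by Bsn, a presynaptic scaffold, with 71 and the postsynaptic scaffold Shank1 with 39. Prrc2b and Tbc1d16 had 38 each, the adhesion receptor Adgrl1 34, Shank3 33, Hcfc1 32, Prrc2a 29 and Shank2 26. At P7 Adcy1 again led with 51, followed by Apc2 with 40, Prrc2b with 39, Prrc2a with 35, Tbc1d16 and Fat2 with 34 each, Adgrl1 with 28, Soga1 with 25, and Bsn and Reln with 24. Fat2 and Reln, 2 genes of the granule cell list, had 7 and 1 peaks at P15. Numbers of peaks per gene carry no error and were not tested.

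No gene list passed the comparison of ages. None of 12 lists passed Fisher's exact test, two-sided, of members among the 730 genes with peaks at P7 only against the 875 with peaks at P15 only; 2 had an unadjusted p under 0.05. Of 28 ion channels and receptors of Purkinje cell firing 13 had a P7 peak and 22 a P15 peak (adjusted p = 0.180), among them the calcium release channel Itpr1 with 18 and 14 peaks and the calcium channel Cacna1g with 7 and 16. Of 20 miRNA pathway proteins 6 and 2 had peaks (adjusted p = 0.256), with 8 peaks at each age in Tnrc6b, whose product binds AGO. Of the other 10 lists the adjusted p was 1.0. Of 26 Purkinje cell markers 12 had a P7 and 14 a P15 peak; Rora had 2 and 11 and Kcna2 0 and 8. Markers of other cells also held peaks, 12 and 13 of 21 granule cell markers (Cntn2 with 12 and 8, Neurod1 with 10 and 7). Of 12 Bergmann glia and astrocyte markers 8 had peaks at each age (Sparcl1 with 9 and 5). Of 12 oligodendrocyte markers 5 did at each age (Mbp with 8 and 5). Among 8 molecular layer interneuron markers only Kit had a peak, at P15. Of 32 postsynaptic scaffolds and adhesion proteins 19 had peaks at each age (Nlgn2 with 13 and 14). Of 51 dendrite and cytoskeleton regulators 27 and 26 did (Map1b with 13 and 3). Of 32 RNA-binding proteins 15 did at each age (Pum2 with 3 and 7). Of 37 chromatin regulators and transcription factors 21 and 25 did (Kmt2d with 18 and 3, Chd7 with 11 and 2).

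Of the 4 genes the study names as miR-206 targets, a list chosen on these samples and so not independent evidence, 3 had peaks at P7 and 4 at P15. Shank3 had 2 peaks at P7, both in the 3' UTR, and 33 at P15, 25 in coding exons and 8 in the 3' UTR. En2, a transcription factor, had 3 and 10, Vash1 2 and 2 and Prag1 0 and 1. In the P15 replicate 2 list 0 of the 4 genes had a peak. None of their sequenced peaks held the 7-nt match to miR-206 nucleotides 2 to 8. A 7-nt match lay within 20 nt of the Prag1 peak in its 3' UTR (chromosome 8, 36147533 to 36147591, plus strand). The 6-nt match lay in a Shank3 coding exon peak at P15 (chromosome 15, plus strand, 89547629 to 89547765) and in overlapping 3' UTR peaks at P7 (89559916 to 89559993) and P15 (89559887 to 89560015), and within 20 nt of an En2 3' UTR peak at P15 (chromosome 5, plus strand, 28170402 to 28170484).

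Whether peaks held sites of the loaded miRNAs was asked with seed matches, the 7-nt complements of miRNA nucleotides 2 to 8, against flanking windows of equal length. No family passed the test at either age. At P7 miR-124-3p matches lay in 20 of 3452 peaks against 10 upstream and 8 downstream windows (adjusted p = 1.0), and those of the family of miR-15, miR-16 and miR-195-5p in 59 against 41 and 42. Matches of the family of miR-1 and miR-206 were in 5 peaks against 18 and 17 windows, and miR-137-3p in 3 against 12 and 12. At P15 miR-129-5p matches lay in 9 of 3705 peaks against 23 and 23 windows, miR-29-3p in 22 against 35 and 23 and miR-124-3p in 18 against 14 and 13. Over the 20 families of at least 1000 CPM together, 10.8% of P7 peaks held a match (exact 95% interval 9.79 to 11.9) against 11.3% upstream and 10.5% downstream, and at P15 10.7% (9.76 to 11.8) against 11.4% and 10.9%. In 3' UTR peaks alone the shares were 10.9% against 12.2% and 12.0% at P7, and 10.4% against 10.8% and 10.4% at P15. No single family passed in 3' UTR peaks alone at either age. The exact McNemar test, two-sided, with adjustment over 46 families and both ages gave 0 calls, with 2 families at P7 and 1 at P15 at an unadjusted p under 0.05, all 3 with fewer matches in peaks. With sites planted in 2% of peaks every planted family was recovered, with sites in 1% all were at P15 and 66.7% at P7, so smaller excesses can be missed; with 6-nt matches the family of miR-1 and miR-206 at P7 and miR-129-5p at P15 were called as fewer in peaks, and with shuffled peaks as background 7 families were called at P7, 4 more and 3 less frequent in peaks, and 5 at P15, 4 more and 1 less frequent.

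**Figure D3:**
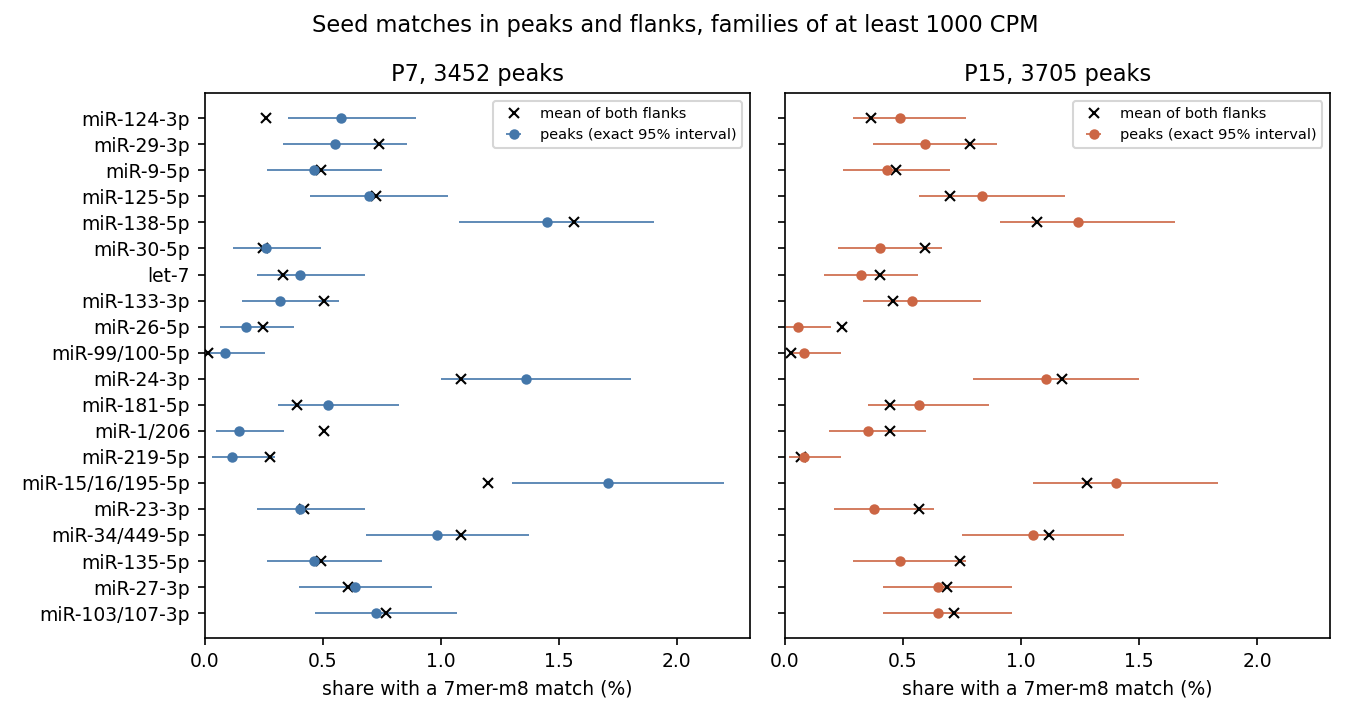
Share of peaks with a 7-nt seed match (percent) for the 20 families of at least 1000 CPM, in order of abundance, with exact 95% intervals, and the mean share of both flanking windows as crosses. At P7 the miR-124-3p share lies above its flanks and the share of miR-1 and miR-206 below, and no family passed the adjusted test.

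Seed matches in peaks listed at 1 age only were compared next. No family passed Fisher's exact test over 46 families; the smallest adjusted p was 0.0883, and 10 families had an unadjusted p under 0.05. Matches of the family of miR-200b, miR-200c and miR-429-3p lay in 19 of 3308 P15-only and 3 of 2740 P7-only peaks, miR-25/92-3p in 13 and 1, and miR-137-3p in 15 and 2, while miR-338-3p matches lay in 13 and 24. With 8mer, 7mer-m8 or 7mer-A1 sites 7 families were called, with 6-nt sites 11 and with peaks extended by 20 nt 9; these settings were not run within 3' UTR or coding exon peaks alone. With 7-nt matches, 0 families within 3' UTR peaks (smallest adjusted p = 0.972) and 1 within coding exon peaks (smallest adjusted p = 0.831) had an unadjusted p under 0.05, against the 10 over all peaks, and 0 were called. Across 34 families of at least 100 CPM, the change of a miRNA family and the log2 ratio of its site shares had a Pearson r of -0.0379 (p = 0.826, permutation test) and a Spearman rho of -0.0590 (p = 0.737, permutation test); without the 2 families farthest from the median change r was -0.0582. These are values across families, which are not independent replicates. With mean CPM in place of its change r was -0.374 (p = 0.0295, permutation test). No family's 7-nt matches passed against flanks, so site shares were not shown to mark bound sites. These correlations therefore cannot decide whether sites follow miRNA levels. The cut of 100 CPM also lies below 229.7 and 439.4 CPM, the limits that a count of 0 allows at P7. Some changes thus rest on few P7 counts, as for miR-25/92-3p with 0 and 439.4 CPM in P7 replicates 1 and 2.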

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

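All tests here other than that on the order of bases were chosen only after the result was seen. In the P15 replicate 2 list the bases TGGAAT began 0 to 5 nt after the end of 14.8% of 596 peaks (exact 95% interval 12.0 to 17.9), above what a count of 0 allows. The main comparisons of ages did not use this list, which entered them only as an alternative. From 12 to 17 nt after the end the share was 0.336%. The bases TGGAAT are the first fixed bases of the 3' adapter, which follow 3 random bases, so the reverse transcription primer annealing to the RNA itself may account for part of these peaks. The starts lay mostly 2 nt (34 peaks) or 4 nt (37 peaks) after the end and seldom 3 nt (3 peaks), a spacing not explained here. The 14.8% share prompted this explanation and so cannot test it, which leaves it open. The other 89 orders of the same 6 bases had a median share of 0.168%, but the highest, GGAATT, reached 6.71%, above the bound set beforehand. GGAATT is itself the adapter's start moved by 1 base, so that bound was poorly chosen and by it base composition cannot be told apart. The medians argue against base composition alone, with 0.168% against 14.8% here, 0.115% against 3.05% at P7 and 0.108% against 2.78% at P15. miR-206 and miR-1 precursors also hold TGGAAT, the first 6 bases of the mature miRNAs; whether that affects their counts was not tested, and no biological explanation was tested.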

How the results depend on the processing

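The thinned libraries and the subsets by location, shared genes, overlap between ages and width were chosen after seeing the data. With these libraries, the P7 ones of 6828 and 13059 counts, 0.5% of simulated 2-fold changes were recovered; depth and spread between libraries were not varied apart. miR-29a-3p, miR-29b-3p, miR-29c-3p and miR-149-5p were called in the 12 alternatives other than thinning. The count of 5 called miRNAs became 16 with no low-count filter, 22 with a mean CPM of at least 10 and 13 with DESeq2; leaving out 1 library gave 6 to 18, with a lone library assumed to vary like the others; the causes were not tested. With the P15 libraries thinned to 9944 counts 5 draws gave 3 to 10 calls, of which 3 to 5 were among the 5. The replicate numbers do not pair animals across ages (correlation of deviations -0.114); with the replicate number as a block 10 were called, without miR-27a-3p. Of 477 values for 37 named miRNAs under alternatives, 400 kept direction and side of the threshold, 37 that were not called changed sign (14 of them with library totals), 35 passed only under the alternative, and 5, all of miR-27a-3p, no longer passed; besides the fit just named these were the thinned draw of median call count (2 of the 5 draws kept all 5 calls) and the fits without P7 replicate 1, P15 replicate 1 or P15 replicate 2. The list count of 1 became 0 with an estimated correlation and with fry, and ranged from 0 to 1 with 1 library left out.

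Peak overlap was 27.2% (P7) and 25.9% (P15) under the stricter rule set relative to the shorter peak, 31.6% and 31.4% with gaps of up to 50 nt, 21.8% and 20.7% for peaks of at least the median width of each list, and 18.3% and 54.9% with the replicate 2 list. The location differences of coding exons and 3' UTRs kept direction and side under all 4 alternatives (coding exon before 3' UTR, the replicate 2 list, genes with peaks at both ages, peaks wider than 30 nt). Other exons no longer passed in shared genes or wider peaks, nor introns in shared genes. The intron difference of -1.29 points became 4.05 with the replicate 2 list and 0.0008, no longer a difference, for peaks wider than 30 nt; the difference outside genes of -2.03 became 26.0 and 1.91; the causes were not tested. Families past the threshold in peaks went from 0 to 1 at each age with 6mer sites and to 7 (P7) and 5 (P15) with shuffled peaks as background. Between the ages they went from 0 to 7 with 8mer, 7mer-m8 or 7mer-A1 sites, 11 with 6mer sites and 9 with peaks extended by 20 nt. The correlation with miRNA change was -0.0752 for families of at least 1000 CPM, 0.019 with the wider site types, 0.188 with the replicate 2 list and 0.054 in 3' UTR peaks. With mean CPM in place of the change it was -0.374. Like the main correlation, these values cannot decide whether sites follow miRNA levels. Alternatives by peak score were not run, since every score is 0.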

Other observations

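Tests in this part were chosen only after the result was seen, except the test of seed matches beside the motif. After the seed tests gave no call, every possible hexamer was compared between 3' UTR peaks and their flanks, and a few longer motifs were then tried; 60 hexamers were more frequent in P15 peaks, led by TGTAAA in 20.1% of peaks against 3.44% upstream and 4.05% downstream (adjusted p = 2.52e-60, exact McNemar test, two-sided). TGTAAA, TGTATA and TGTACA, ranked 1, 2 and 4, are parts of a motif known to be bound by Pumilio proteins, TGTA followed by A, C or T and ATA. This motif lay in 24.1% of 2150 P15 3' UTR peaks (exact 95% interval 22.3 to 26.0) against 1.35% and 1.67% of flanks, in 15.5% of 910 P7 3' UTR peaks against 1.87% and 1.43%, and in 21.2% of 340 such peaks of the replicate 2 list. En2 had 2 motif peaks at P7 and 4 at P15, Kcna2 0 and 5 and Lnpep 0 and 5; these genes were chosen after their values were seen. At P7 the hexamer GAAGAA was more frequent in coding exon peaks than in their flanks, 9.55% against 5.10% and 5.76% (adjusted p = 0.000524, exact McNemar test, two-sided). ACAACA was less frequent in these peaks, 0.735% against 3.06% and 2.53% (adjusted p = 0.000524, same test). The ages were not compared for these hexamers.

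For this motif, base composition is argued against by dinucleotide-shuffled copies of the P15 peaks, of which 1.89% held the motif, and signal from the other strand by the reverse complement, found in 4.0%. The explanation that motif sites were held next to seeds of abundant miRNAs predicts more such seeds beside the motif, which was not found. Such a seed lay within 20 nt of 13.2% of 629 motif peaks against 18.4% of 1935 others (odds ratio 0.674, 95% interval 0.514 to 0.877, Fisher's exact test p = 0.00231). These counts include 3' UTR peaks lacking a full flank, left out of the 2150 above. Seeds of these families lay in 10.4% of P15 3' UTR peaks against 10.8% of upstream and 10.4% of downstream windows. A seed match was therefore not shown to mark bound sites here, and base content was not matched, so the test cannot decide. Proteins other than AGO2 retained in the pull-down stay open, as does age, and were not tested. Peaks that overlapped between the ages held the motif in 29.8% (P7) and 31.0% (P15) of 3' UTR peaks. It lay in 480 of 2084 P15-only and 24 of 528 P7-only 3' UTR peaks (odds ratio 6.28, Fisher's exact test p = 4.87e-27). The motif was chosen after hexamers of it led the scan of the same P15 peaks, and peaks are not replicates of an age. The test therefore compares the lists and cannot decide whether the motif differs with age.

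The shift from coding exons at P7 to 3' UTRs at P15 was weighed next. Different genes at the 2 ages are argued against by the 935 genes with peaks at both ages. In these the 3' UTR share still differed by 24.4 points, 25.5% against 49.9%. It was higher at P15 in 474 genes and lower in 88 (exact sign test p = 6.23e-65). Genes are not replicates of an age, so the sign test compares the lists. A property of 1 P15 list cannot be told apart. In the replicate 2 list 66.8% of the 612 peaks in 3' UTRs or coding exons lay in 3' UTRs, nearer to the 60.4% at P15 than to the 25.5% at P7. Of all its 1624 peaks 25.2% did, nearer to the 20.6% at P7 than to the 49.9% at P15. Whether the lists are independent is not known. The replicate 2 list may be part of the pooled P15 data, another version of the P15 list, or a replicate that the P15 list leaves out. More unbound mRNA in the P7 pull-down, a different depth of the target libraries, and age itself stay open, were not tested and may all contribute; input and target reads were not analysed here.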
